A study of Mus musculus with 15 samples.

How the data were processed

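RNA from dissected proximal and distal convoluted tubules of wild-type and Cldn10a knockout mouse kidneys was sequenced in 15 libraries, on GRCm38. Per the labels, RNA was isolated with a micro column kit and libraries were made with Nextera XT. The submitters' processing notes name CASAVA 1.8, STAR 2.5 and DESeq2 1.24.0. The counting program, its annotation release and its strand setting are not given in the sources used here, so reads of antisense genes and of near-identical copies are uncertain.

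The deposited count table holds whole numbers per gene and library, which the authors call raw counts. The space-separated layout and all-digit column names of this deposited file were not recognised as a count table by the format check applied, so its unit was recorded as other, although the values are whole-number counts and were analysed as such. The authors also deposited 2 tables of log2 fold changes, p values and adjusted p values, whose unit is likewise recorded as other; they were used only for comparison. The design formula of those tables and the sign of their fold change are not stated, and the sign was read from Cldn10. The count table holds 54752 genes, of which 54723 have a symbol in GENCODE M21 and 24945 have no count in any library. All 15 columns were matched to samples.

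The test planned before the data were examined was a quasi-likelihood count test. Since the unit was recorded as other, that planned test is not part of the results, and the planned DESeq2 alternative was not run. A trial run of the quasi-likelihood test was made on the same counts; it differed from limma in calling some genes for the interaction, where limma called none, and its values are not reported here. limma 3.58.1 in R 4.3.3 was used instead, with voom weights on log2 CPM (prior count 0.5) and moderated linear models. limma was chosen before the results of either test were seen. Scale factors were trimmed means of M values (30% of log ratios and 5% of intensities trimmed), and a gene was kept with a count of about 10, scaled to library size, in as many libraries as the smallest group holds and a total of 15. Cldn10 was exempt from this filter and was left out of the list tests. CPM given with an SD come from 1 scaling of all 15 libraries.

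The 3 within-segment or between-segment contrasts were knockout against wild type in proximal tubule, the same in distal tubule, and proximal against distal in wild type; the fourth test was the interaction of genotype and segment. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Single values were compared with an exact two-sided permutation test. 43 gene lists (27 of processes and 16 of cell types), fixed before the data were examined, were tested where at least 5 members passed the filter, with camera (preset correlation 0.01, and again with an estimated correlation) and fry, which asks whether a list's genes change, on balance one way or in either direction, and compares them with no other genes. The contrasts, lists, naming rule, thresholds and first alternatives were all set before the data were examined.

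Genes were named by a fixed rule: Cldn10, Cldn2 and the claudins past the filter; up to 10 higher and 10 lower genes by smallest p among called genes with a log2 change of at least 1 in size, a mean of at least 2 CPM, groups fully apart and a symbol that is not a predicted one; and up to 4 members with the smallest p of each list described. Between segments it was up to 5 higher and 5 lower, of which 1 is not reported here. Where fewer than 5 passed, the 5 with the smallest p in each direction were named as having failed.

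The libraries held 28729339 to 51764746 counts (median 42660626), of which 18.3 to 29.2% were of protein-coding genes, and 17941 to 19880 genes were detected. Where a gene had no count in a group, the bound used 3 counts per library; bounds and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of replicates was a copy of another (Pearson r of log2 values 0.925 to 0.965).

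The pipeline was tested on simulated data with 200 genes changed. For proximal tubule it called 28.1% of genes changed 2-fold and 82.7% of those changed 4-fold, with 7 false calls among 12799 genes. It called 5 of 5 raised lists and 0 of 20 unchanged lists. Each simulated gene had the spread typical of its expression level. The shares called need not hold for genes that vary more, or where fewer genes change. The simulated genes varied independently and the raised lists held genes raised 2-fold or 4-fold. The list result therefore does not show how camera treats correlated genes or smaller shifts. In the real proximal data the estimated correlation of the ribosomal list was 0.76.

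The alternatives planned before the data were examined were median-of-ratios scaling, no filter, a stricter filter (10 counts in every library of a group), sample quality weights, 1 fit of all 15 libraries, an adjusted p under 0.1, leaving out each library in turn, the series of the label number as a covariate or its larger part alone, a replicate block, and knockout libraries in place of wild type. Chosen after seeing the data were nuclear protein-coding genes only, removal of the exon length and GC trend in each library, and 2 scores as covariates. Genes that did not pass the filter were left out of the tests because their counts were too low.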

Results

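RNA was sequenced from tubules dissected from mouse kidneys that carried or lacked claudin-10a, a tight junction protein encoded by Cldn10. The 15 libraries fall into 4 groups: wild-type proximal convoluted tubule (n = 4), knockout proximal convoluted tubule (n = 3), wild-type distal convoluted tubule (n = 4) and knockout distal convoluted tubule (n = 4). Per the labels, pools held 10 proximal or about 20 distal tubules per kidney. The labels do not say outright that each library comes from a different animal, so p values measure the spread between these samples.

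The proximal wild-type libraries held 42463035, 41982213, 36056160 and 44895494 counts (replicates 1, 2, 3 and 6), and the proximal knockout libraries 28729339, 39331088 and 34583314 counts (replicates 4, 5 and 7). The distal wild-type libraries held 38330040, 47061084, 45755319 and 44503067 counts (replicates 1 to 4), and the distal knockout libraries 42660626, 45365070, 51764746 and 45008767 counts (replicates 5 to 8). Mitochondrial ribosomal RNA took 57.8 to 71.6% of the counts, and nuclear protein-coding genes took 8.02 to 19.8%. Xist, the RNA of the inactive X chromosome, had 0 to 2 counts per library, while the chromosome Y genes had 625 to 1460. By these counts every library came from male tissue.

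Cldn10, the targeted gene, was read first, to see in which segment its RNA was lost. Cldn10 (ENSMUSG00000022132; GRCm38 chromosome 14, 118787908 to 118875489, + strand) had 21.8 ± 8.77 CPM (counts scaled to library size; SD, n = 4) in wild-type proximal tubule, from 541 to 1514 counts per library. It had 0 counts in each of the 3 knockout proximal libraries, at least 259-fold lower with a floor of 3 counts per library. The exact two-sided permutation test over 35 arrangements gave p = 0.0571, where the smallest possible is 0.0286, and the limma test across all genes gave an adjusted p of 0.0271. In distal tubule, Cldn10 had 0.23 ± 0.187 CPM in wild type (SD, n = 4; 3 to 22 counts) and 0.232 ± 0.284 CPM in knockout (SD, n = 4; 0 to 24 counts), with an exact permutation p of 1 over 70 arrangements. The limma log2 change of Cldn10 in distal tubule was −1.34 ± 1.16 (SE, adjusted p = 0.824), on few counts, and the test between segments rests in part on it. The limma test of the difference between the segments' changes in Cldn10 gave −9.29 ± 2.26 (log2, SE) with an adjusted p of 0.494. The call in proximal tubule was lost without knockout replicate 4, 5 or 7 (adjusted p = 0.355, 0.417 and 0.255; the range over all alternatives was 3.26e-07 to 0.456), while Cldn10 still had 0 counts in every knockout library left. Counts are per gene, so the isoforms of Cldn10 were not separated.

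The series asks about claudin-2, a claudin that forms pores for cations and water, and about chloride permeability. Cldn2 (ENSMUSG00000047230; chromosome X, 139800828 to 139811386) had 153 ± 19.4 CPM in wild-type proximal tubule (SD, n = 4) and 156 ± 1.45 CPM in knockout (SD, n = 3), a log2 difference of 0.04 ± 0.14 (SE) with a limma adjusted p of 0.97. Its log2 difference was −0.01 without wild-type replicate 6 and 0.12 at the other end of the leave-one-out range, so neither direction held. Among the other claudins of proximal tubule, Cldn12 had 27.2 ± 1.98 CPM in wild type and 28.2 ± 2.24 CPM in knockout, Cldn1 had 11.9 ± 3.82 and 9.85 ± 5.01 CPM, and Cldn18 had 0.278 ± 0.0835 and 0.704 ± 0.276 CPM (log2 difference 1.27, adjusted p = 0.594). In distal tubule, Cldn8 had 79.7 ± 10.8 CPM in wild type and 80.6 ± 14.2 CPM in knockout, Cldn7 had 4.67 ± 0.856 and 3.85 ± 0.975 CPM, Cldn4 had 3.05 ± 1.31 and 3.1 ± 1 CPM, and Cldn6 had 0.61 ± 0.234 and 1.29 ± 0.634 CPM (log2 difference 1.003, adjusted p = 0.687). With Cldn10 left out, 0 of 6 claudins in proximal tubule and 0 of 10 in distal tubule changed in the limma test over all genes, and 0 and 0 adjusted over the list alone. At an unadjusted p under 0.05 there was 1 in each segment, Cldn18 in proximal and Cldn6 in distal tubule; voom with sample quality weights called none of the claudins named here other than Cldn10.

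**Figure D1:**
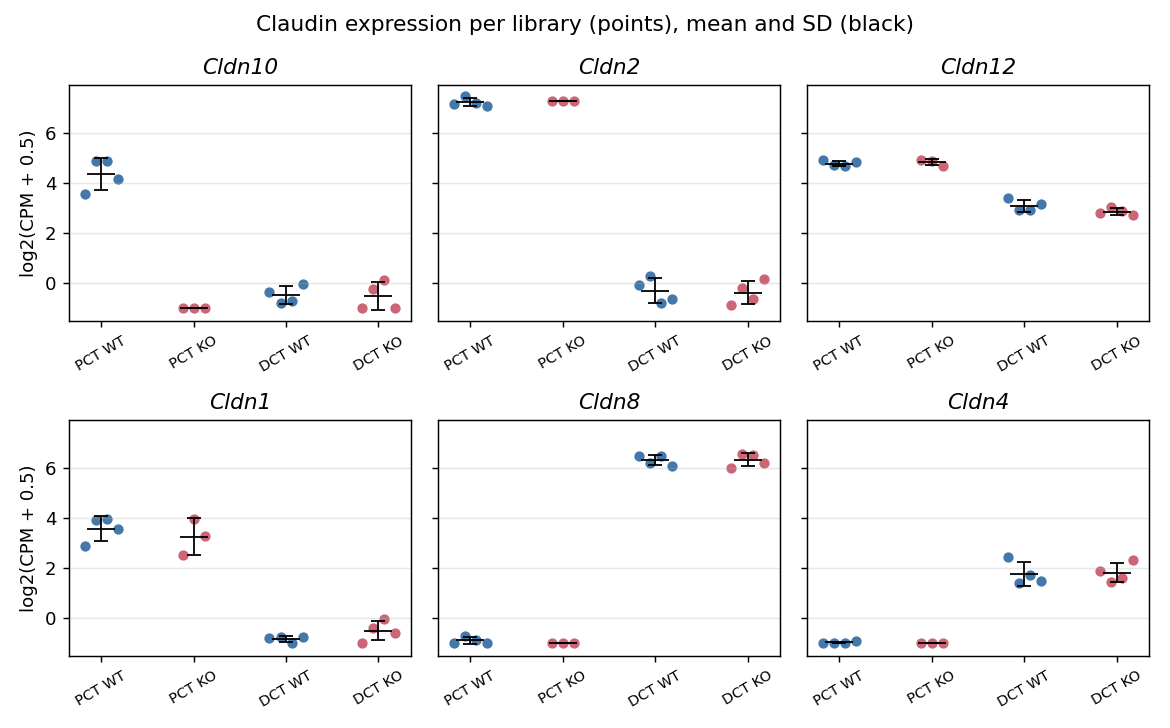
Log2(CPM + 0.5) of claudin genes by segment and genotype (PCT, proximal; DCT, distal convoluted tubule; WT, wild type; KO, knockout), with 1 point per library and the mean and SD in black. Cldn10 sits at 0 counts in the 3 knockout proximal libraries, while Cldn2 has 153 CPM in wild-type and 156 CPM in knockout proximal tubule.

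In proximal tubule, the knockout was compared with wild type to find genes other than Cldn10 whose RNA differs. Lpl, which encodes the lipase that releases fatty acids from lipoproteins (ENSMUSG00000015568; chromosome 8, 68880491 to 68907448), rose from 21 ± 9.68 CPM (SD, n = 4) to 75.2 ± 24.3 CPM (SD, n = 3), a log2 change of 1.89 ± 0.29 (SE) with an adjusted p of 0.027. Cd36, a fatty acid uptake receptor, rose by 2.60 ± 0.47 on the log2 scale (adjusted p = 0.0476), from 14.8 ± 11.5 to 70.2 ± 21.8 CPM. Gsta4, a glutathione transferase that clears lipid aldehydes (ENSMUSG00000032348; chromosome 9, 78182774 to 78209349), fell from 8.88 ± 2.57 to 1.77 ± 0.43 CPM, a log2 change of −2.30 ± 0.33 (adjusted p = 0.027). Abcc4, an exporter of organic anions that lies next to Cldn10 (chromosome 14, 118482692 to 118706219), rose from 10.9 ± 2.18 to 25.9 ± 7.05 CPM, a log2 change of 1.243 ± 0.214 (adjusted p = 0.0381). limma called 22 of 13229 genes in all, 13 higher and 9 lower in knockout.

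Of the other genes that rose, Atp11a, a phospholipid flippase, went from 39.6 ± 14.8 to 115 ± 11.9 CPM (log2 change 1.62 ± 0.25). Acy3, an aminoacylase, went from 233 ± 45.3 to 506 ± 118 CPM (1.12 ± 0.19). Ces1f, a carboxylesterase, went from 74.5 ± 15.2 to 151 ± 9.33 CPM (1.05 ± 0.17). Pzp, a protease inhibitor, went from 3.83 ± 2.52 to 19.7 ± 7.99 CPM (2.53 ± 0.39), and Akr1c14, a steroid dehydrogenase, from 2.96 ± 2.01 to 19.3 ± 7.69 CPM (2.90 ± 0.44). Ace, which makes angiotensin II, went from 4.13 ± 2.12 to 17.5 ± 6.67 CPM (2.16 ± 0.36), and Tmem252 from 12.1 ± 2.5 to 29.1 ± 6.22 CPM (1.26 ± 0.20). Cyp4a12a, a fatty acid hydroxylase, went from 22.9 ± 5.12 to 64.2 ± 19.3 CPM (1.47 ± 0.24) and its copy Cyp4a12b from 15.9 ± 1.23 to 31.4 ± 5.19 CPM (0.98 ± 0.16). The copies are near-identical, so which of the Cyp4a12 genes rose is uncertain. The adjusted p of these genes lay between 0.027 and 0.0381, and the remaining called gene that rose, Gm48931, had a log2 change of 1.10.

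Of the other genes that fell, Gsta2, a glutathione transferase, went from 181 ± 14 to 89.5 ± 11.8 CPM (log2 change −1.02 ± 0.15, adjusted p = 0.027). Gm10639, a near-identical gene of the same family, fell by 1.03 on the log2 scale, so which copy fell is uncertain. Ugt2b34, which adds glucuronic acid to lipophilic compounds, went from 33.8 ± 8.88 to 12.7 ± 3.45 CPM (−1.40 ± 0.24, adjusted p = 0.0381). Slc7a2, a transporter of cationic amino acids, went from 7.37 ± 0.769 to 2.52 ± 1.43 CPM (−1.69 ± 0.30, adjusted p = 0.0459). The small RNA genes Gm26035, Gm24146 and Gm26315 fell, with log2 changes from −1.33 to −1.11, and their near-identical copies make the source of those reads uncertain. Cyp4a12b, Gm48931, Gm10639 and the small RNA genes fell outside the naming rule and were chosen after their values were seen.

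The 21 called genes other than Cldn10 kept their direction under every scaling, filter, weighting, covariate or removal of 1 library set beforehand, but the count of 22 fell to 2 without wild-type replicate 1, 7 without wild-type replicate 2, 9 without wild-type replicate 3, 4 without knockout replicate 4, 6 without knockout replicate 5 and 10 without knockout replicate 7. Of the 21, these removals left 0, 5, 6, 4, 4 and 5 called, and 9 stayed called without wild-type replicate 6, so some of the genes counted were newly called. The balance of higher and lower genes turned from 13 and 9 to 1 and 8 without wild-type replicate 3 and 1 and 5 without knockout replicate 5. It became more one-sided, at 9 and 1, without knockout replicate 7. The groups did not overlap for 7.9% of tested genes, where chance gives 5.7%.

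**Figure D2:**
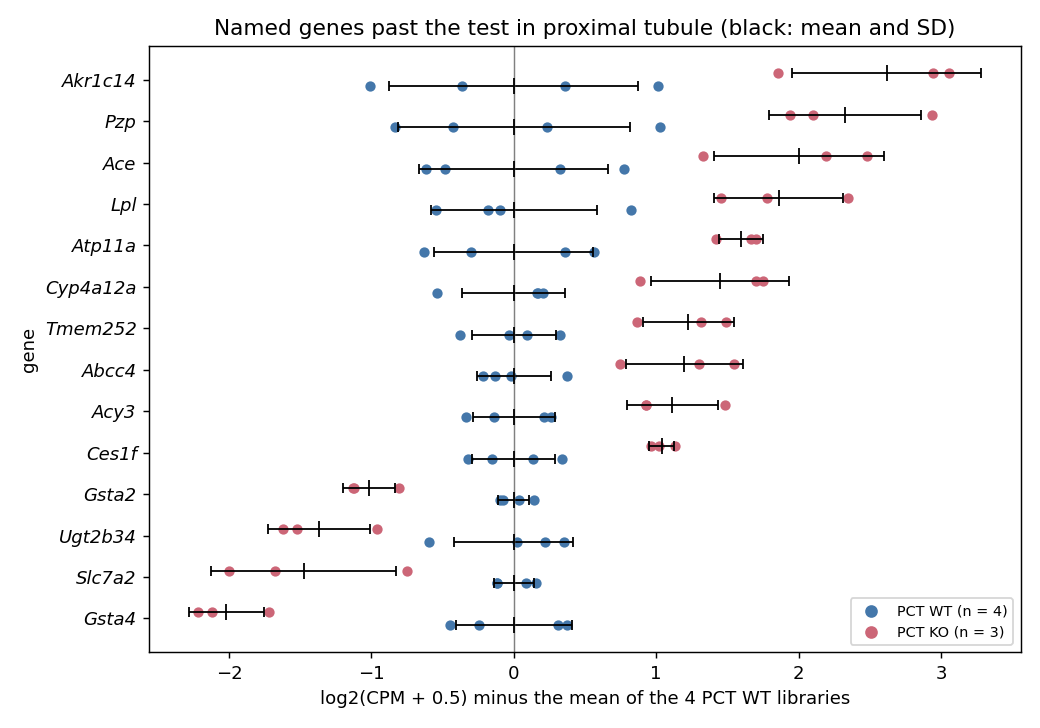
Log2(CPM + 0.5) of named genes called in proximal tubule, minus the mean of the 4 wild-type libraries, with 1 point per library and the mean and SD in black. Lpl, Ace and Abcc4 are higher, and Gsta4, Gsta2, Ugt2b34 and Slc7a2 lower, in the 3 knockout libraries than in the 4 wild-type libraries.

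Gene lists fixed before the data were examined were tested with camera to see whether whole processes or cell types moved in proximal tubule. Genes of the straight segment were called higher by camera (13 genes, median log2 change 1.31, adjusted p = 2.0e-13, or 0.144 with an estimated correlation). All 13 changes were above 0, with 2 called over all genes (Atp11a and Acy3) and 7 adjusted over the list alone. Aadat, an enzyme of tryptophan breakdown, and Ghr, the growth hormone receptor, belong to this list and had log2 changes of 0.90 and 0.63. Genes of the early segments were called lower by camera (16 genes, median −0.31, adjusted p = 0.000729, or 0.350 with an estimated correlation). Over all genes 0 were called, and 5 were lower adjusted over the list alone. Among these, Slc5a2, the glucose transporter of the early tubule, had a log2 change of −0.81 (adjusted p = 0.296), Spp2 −0.98, Slc7a7 −0.58 and Slc4a4 −0.42.

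Organic anion and cation transporters were called higher by camera (25 genes, median 0.61, adjusted p = 9.9e-11, or 0.0807 with an estimated correlation). Over all genes 1 was called (Abcc4), and 8 adjusted over the list alone. Slco1a1, an organic anion uptake transporter, had 5.94 ± 6.36 CPM in wild type and 43.0 ± 22.6 CPM in knockout (log2 change 3.78, adjusted p = 0.0572), and Slc17a3 and Slco1a6 had log2 changes of 0.85 and 0.84. Fatty acid oxidation and PPAR target genes were called higher by camera (36 genes, median 0.32, adjusted p = 1.2e-05, or 0.295 with an estimated correlation). Cyp4a12a and Cd36 were called over all genes, and 9 were higher and 1 lower adjusted over the list alone. Ehhadh, an enzyme of peroxisomal fatty acid oxidation, had a log2 change of 0.85, and Acot12, which splits acetyl-CoA, 0.95.

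Genes known to be higher in male proximal tubule were called higher by camera (17 genes, median 0.79, adjusted p = 2.0e-13, or 0.135 with an estimated correlation). Of these, 0 rose and 1 fell (Gsta4) over all genes, against 11 and 1 adjusted over the list alone. Cndp2, a dipeptidase, and Ugt8a had log2 changes of 1.04 and 0.94. Genes known to be higher in females were called higher by camera as well (13 genes, median 0.35, adjusted p = 0.00332, or 0.144 with an estimated correlation). Over all genes 1 was called (Abcc4), and 2 adjusted over the list alone. Cyp2a4, a steroid hydroxylase, had a log2 change of 2.10 and Cyp2a5 0.58. With 0 to 2 Xist counts in every library, a difference in sex between the groups is argued against. The male list shares 4 of its 20 genes with the straight-segment list and 4 with the organic anion and cation transporters. Those transporters share 3 genes with the straight-segment list. Abcc4 belongs to the transporter list, the female list and the list of neighbours of Cldn10. The calls of these lists are therefore not independent.

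Neighbours of Cldn10 on chromosome 14 were called higher by camera (19 genes, median 0.23, adjusted p = 0.00967, or 0.161 with an estimated correlation). Abcc4 was called over all genes and adjusted over the list alone. Tmtc4 and Dnajc3, both of the endoplasmic reticulum, had log2 changes of 0.77 and 0.56. Endothelial genes were called higher by camera (16 genes, median 0.57, adjusted p = 1.2e-05, or 0.551 with an estimated correlation), with 0 genes called either way. The receptors Kdr and Flt1 had log2 changes of 0.79 and 0.72, and Cdh5 and Adgrf5 0.99 and 0.92.

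Cytosolic ribosomal protein genes were called lower by camera (80 genes, median −0.29, camera adjusted p = 5.9e-11; adjusted p = 0.692 with an estimated correlation), and so were oxidative phosphorylation genes (90 genes, median −0.29, camera adjusted p = 5.9e-11; adjusted p = 0.692 with an estimated correlation), with 0 called either way in both. Both rest on knockout replicate 5, without which the medians were 0.00532 and −0.0296. The mean ribosomal score of the other 2 knockout libraries was 0.148, against 0.142 in wild type, and the oxidative phosphorylation score 0.089 against 0.13. Rps21 had a log2 change of −0.82 and Cox6c −0.63. Without knockout replicate 5 the camera calls of the ribosomal list (adjusted p = 0.992), the oxidative phosphorylation list (0.238) and the neighbours of Cldn10 (0.181) were lost. The median of the neighbours was then 0.109. camera called 10 of 34 lists, 7 up and 3 down, and 0 held with an estimated correlation in proximal tubule. The estimated correlation was −0.015 for the female list and 0.0011 for the neighbours of Cldn10, both below the preset 0.01. For these lists a higher correlation between genes is therefore not why the call was lost. fry called 0 lists for one direction on balance (lowest adjusted p = 0.0845) and 13 for a change in either direction.

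**Figure D3:**
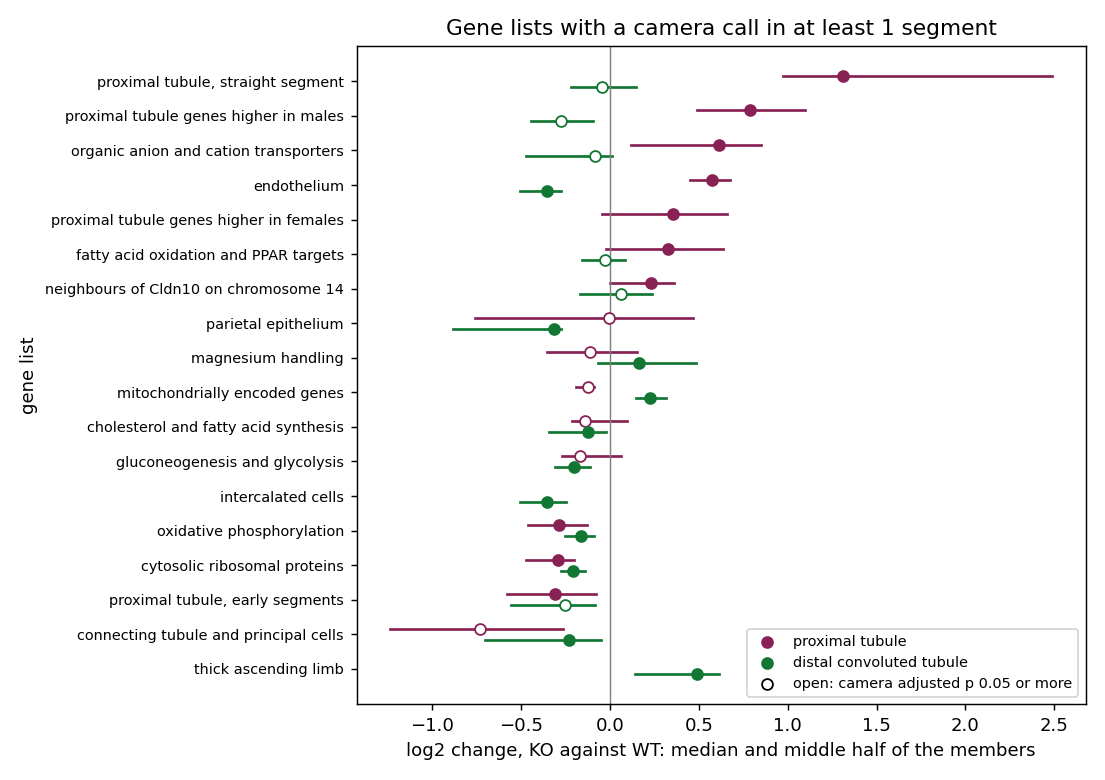
Median log2 change, knockout against wild type, of the gene lists called by camera in at least 1 segment, in proximal and in distal tubule, with bars between the quartiles of the list members and open points where camera made no call. The straight-segment list lies at 1.31 and the early-segment list at −0.31 in proximal tubule.

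In distal tubule, the knockout was compared with wild type to see whether a segment with little Cldn10 RNA differed. Atrx, a chromatin remodeller, had 15.3 ± 2.18 CPM in wild type (SD, n = 4) and 26.4 ± 4.96 CPM in knockout (SD, n = 4), a log2 difference of 0.78 ± 0.16 (SE; limma adjusted p = 0.524). Nab1, a transcriptional co-repressor, had 5.86 ± 1.38 and 10.1 ± 0.734 CPM (0.81 ± 0.18), and Tmtc4 had 1.92 ± 0.246 and 3.64 ± 0.501 CPM (0.94). mt-Nd4l, a subunit of complex I, had a log2 difference of 0.54, and Cyp2j11, a cytochrome P450, of 0.90. On the lower side, Eng, an endothelial receptor, had 6.02 ± 1.34 and 3.42 ± 0.741 CPM (−0.82 ± 0.21), and S100g, a calcium-binding protein of the distal tubule, had 1370 ± 304 and 928 ± 172 CPM (−0.54 ± 0.15). Habp2, Map1lc3a and Sparc had log2 differences of −0.87, −0.93 and −0.63. These 10 genes have the smallest p in each direction under the naming rule, and all failed the test. limma called 0 of 12969 genes, with 925 at an unadjusted p under 0.05 and a lowest adjusted p of 0.524; voom with sample quality weights also called 0. The groups did not overlap for 3.8% of genes, where chance gives 2.9%. In simulated data at this group size with 200 genes changed, 95.8% of genes set 4-fold apart and 52.6% of those set 2-fold apart were called. Each simulated gene had the spread typical of its expression level, and the adjusted p is stricter where fewer genes change. These shares therefore do not say how many real changes of those sizes would have been called.

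Among the lists in distal tubule, camera called the 13 mitochondrially encoded genes higher (median log2 change 0.23, adjusted p = 2.4e-08, or 0.237 with an estimated correlation). All 13 were above 0, and 4 passed adjusted over the list alone: mt-Nd4l, mt-Nd4, mt-Nd5 and mt-Nd2, with 0.54, 0.41, 0.43 and 0.32. Thick ascending limb genes were called higher by camera (11 genes, median 0.49, adjusted p = 0.00123, or 0.425 with an estimated correlation). Of these, 3 passed adjusted over the list alone: Slc12a1, the sodium-potassium-chloride cotransporter, at 1.02, Ptger3, a prostaglandin receptor, at 0.80, and Umod, which encodes uromodulin, at 0.52. Magnesium handling genes were called higher by camera (17 genes, median 0.17, adjusted p = 0.0312, or 0.527 with an estimated correlation).

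Ribosomal protein genes were called lower by camera (81 genes, median −0.21, adjusted p = 5.6e-12, or 0.527 with an estimated correlation). So were oxidative phosphorylation genes (89 genes, median −0.16, camera adjusted p = 3.3e-09, or 0.527 with an estimated correlation). Rps15 had a log2 difference of −0.52 and Ndufs7 −0.46. Endothelial genes were called lower by camera (17 genes, median −0.36, adjusted p = 5.3e-07, or 0.237 with an estimated correlation). All 17 were below 0, and only Eng was lower adjusted over the list alone. Intercalated cell genes were called lower by camera (15 genes, median −0.36, adjusted p = 4.9e-07, or 0.425 with an estimated correlation). Kit and Slc4a9, a chloride-bicarbonate transporter, had −0.63 and −0.48. Connecting tubule and principal cell genes were called lower by camera (14 genes, median −0.23, adjusted p = 7.7e-05, or 0.425 with an estimated correlation). Apela (−1.54) and Tmem45b (−0.67) were lower adjusted over the list alone. Aqp3, a water and glycerol channel, had −0.99. Glycolysis and gluconeogenesis genes were called lower by camera (18 genes, median −0.20, adjusted p = 0.000491, or 0.425 with an estimated correlation). So were parietal epithelium genes (5 genes, −0.31, 0.0187, or 0.377 with an estimated correlation) and cholesterol synthesis genes (23 genes, −0.13, 0.0415, or 0.698 with an estimated correlation). None of these list members passed over all genes. camera called 11 of 37 lists, 3 up and 8 down, of which 0 held with an estimated correlation in distal tubule. fry called 0 for one direction on balance (lowest adjusted p = 0.137) and 1 for either direction, the neighbours of Cldn10 (adjusted p = 0.0432). Without knockout replicate 5 the number of lists called fell to 7, losing the connecting tubule (adjusted p = 0.0698), parietal (0.232), cholesterol (0.344) and magnesium (0.344) calls; without knockout replicate 6 it was 17. Calls were also lost without knockout replicate 7 (glycolysis 0.0562, cholesterol 0.179), knockout replicate 8 (parietal 0.051), wild-type replicate 1 (magnesium 0.117), 2 (magnesium 0.116), 3 (thick ascending limb 0.0598, magnesium 0.0858) and 4 (cholesterol 0.952, parietal 0.0661). Without wild-type replicate 3 the thick ascending limb median was 0.148, and without wild-type replicate 4 the cholesterol median turned to 0.0209. The magnesium, parietal, connecting tubule and cholesterol medians were 0.0711, −0.161, −0.149 and −0.0858 without knockout replicate 5. The glycolysis median was −0.0899 without knockout replicate 7.

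Whether the knockout acted differently in the 2 segments was tested directly as an interaction over all 15 libraries. Gsta4 had a difference of −2.16 ± 0.37 on the log2 scale (SE; limma adjusted p = 0.118), as it went from 8.88 to 1.77 CPM in proximal tubule and from 41.4 ± 5.55 to 38.0 ± 7.77 CPM in distal tubule (n = 4 and 4). Lpl had a difference of 1.38 ± 0.33 (adjusted p = 0.494), with 34.3 ± 8.2 CPM in wild-type and 48.3 ± 2.65 CPM in knockout distal tubule. Atp11a had 1.68 ± 0.37 (adjusted p = 0.460), and Abcc4 had 0.57 ± 0.35 (adjusted p = 0.955). limma called 0 of 15279 genes, with 849 at an unadjusted p under 0.05, and voom with sample quality weights called 0. A trial quasi-likelihood test of the same counts did call some genes for the interaction, so whether any gene is called depends on the test. In simulated data with 200 genes changed, 57% of differences of 4-fold and 4% of differences of 2-fold were called. The limits of the simulation given for distal tubule hold here as well.

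Wild-type proximal and distal tubules were compared to see how cleanly the segments were separated. Slc34a1, the phosphate transporter of the proximal brush border, had 1200 ± 158 CPM in proximal and 0.886 ± 0.4 CPM in distal tubule (SD, n = 4 and 4). Slc12a3, the thiazide-sensitive sodium chloride cotransporter, had 0.273 ± 0.0454 CPM in proximal and 669 ± 111 CPM in distal tubule. Lrp2, the endocytic receptor megalin, had 1700 ± 189 and 10.0 ± 1.18 CPM (log2 difference 7.37 ± 0.13, limma adjusted p = 2.5e-15), and Klk1, a kallikrein, had 0.776 ± 0.138 and 3340 ± 515 CPM (−12.10 ± 0.28, adjusted p = 2.7e-14). limma called 6631 of 13616 genes, 3210 higher and 3421 lower in proximal tubule, and the groups did not overlap for 45% of genes, where chance gives 2.9%.

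Other genes higher in proximal tubule were Cltrn, a partner of amino acid transporters, Gpx3, a secreted glutathione peroxidase, and Acsm2, with log2 differences of 7.69, 6.41 and 8.85. Lower were Wnk1, a kinase that regulates the distal cotransporter, Nudt4, S100g and Tmem52b, with −5.35, −4.32, −9.88 and −10.66. Distal tubules also held Umod at 166 ± 64.3 CPM, Slc12a1 at 45.4 ± 27.7 CPM, Slc4a1, an anion exchanger of intercalated cells and red blood cells, at 20.3 ± 3.87 CPM, and Aqp2, the water channel of principal cells, at 4.25 ± 2.46 CPM, against 0.0268, 0.284, 0.0115 and 0 CPM in proximal tubule. Slc34a1, Slc12a3, Umod, Slc12a1, Slc4a1 and Aqp2 fell outside the naming rule and were chosen after their values were seen. Of the claudins, Cldn10, Cldn2, Cldn1 and Cldn12 were higher in proximal tubule, with log2 differences of 6.72, 9.16, 7.60 and 1.73, and Cldn8, Cldn7 and Cldn4 lower, with −11.46, −8.84 and −7.67.

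Between the segments, camera called 21 of 37 lists, 10 higher and 11 lower in proximal tubule, and 9 of these held with an estimated correlation. Among the 9, all 16 early-segment genes were higher (camera adjusted p = 7.4e-14; adjusted p = 0.0283 with an estimated correlation), as were 25 of 27 sodium-coupled transporters (adjusted p = 0.00518 with an estimated correlation). All 13 distal convoluted tubule genes (adjusted p = 0.00684 with an estimated correlation) and all 15 intercalated cell genes (0.0254) were lower. Of 15 connecting tubule and principal cell genes, 12 were lower and 1 higher (adjusted p = 0.0283 with an estimated correlation).

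The deposited tables of the same contrasts were read for comparison. They belong to the same series of libraries, so agreement in sign and size is largely given in advance and adds no independent support. The submitters' notes name DESeq2, where limma was used here, so the numbers of calls come from different tests. The authors' table for proximal tubule called 136 genes, 84 higher and 52 lower in knockout, and 21 of the 22 genes called here were among them. Of the 136, 133 were tested here and all 133 had the same sign, and the log2 changes had a Pearson r of 0.936 across 13229 genes, which are not independent replicates. The authors' table for distal tubule called 3 genes, Atrx (0.80), Nab1 (0.80) and AC134468.1 (1.01), with r = 0.932 across 12969 genes. The authors' log2 change of Cldn10 was −12.2 in proximal and 0.0363 in distal tubule, and the negative sign in proximal tubule means lower in knockout in those tables. AC134468.1 was named after its values were seen, as 1 of only 3 genes.

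**Figure D4:**
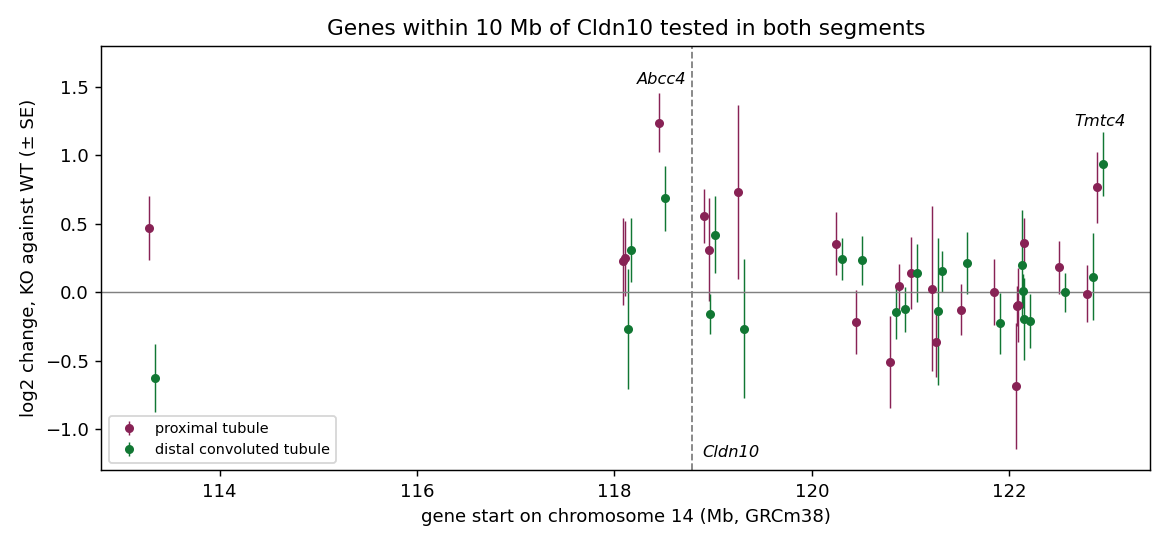
Log2 change, knockout against wild type, of genes within 10 Mb of Cldn10 that were tested in both segments, by gene start on chromosome 14 (GRCm38), with SE bars. Abcc4 (1.243 in proximal and 0.69 in distal tubule) and Tmtc4 (0.77 and 0.94) lie above 0 in both segments.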

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

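The tests of single libraries were set beforehand, and the tests that weigh explanations for PCT knockout replicate 5 were chosen only after the result was seen. In 209 groups of 4 libraries tested for a single library far from the others, 10 stood out, where chance gives about 10.5. The measure is the gap to the nearest library over the whole range of the group on the log2 CPM scale.

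In wild-type proximal tubule, replicate 6 stood low for Cyp4a12a (0.944) and Acsm2 (0.88), and replicate 1 stood high for Slc4a4 (0.924). In wild-type distal tubule, replicate 3 stood low for Pfkl (0.831), and replicate 4 stood low for Apela (0.952) and high for Lad1 (0.841). In knockout distal tubule, replicate 8 stood high for mt-Nd4l (0.856), and replicate 5 stood high for Trpm6 (0.866) and low for Ptger3 (0.855) and Aqp3 (0.85).

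Ribosomal protein and oxidative phosphorylation genes stood low in knockout proximal replicate 5, a group of 3 that the rule above leaves out: the mean log2 score of the ribosomal list was −0.864 there and 0.021 to 0.263 in the other 6 libraries, and that of oxidative phosphorylation was −0.697 against 0.028 to 0.203. Exon length and GC bias is argued against as the whole source, since with that trend removed per library the ribosomal score was still −0.617 against 0.031 to 0.214. With nuclear protein-coding genes only, the ribosomal score was −0.9 against 0.03 to 0.275. This cannot decide whether a few genes taking most of the counts is the source. The scale factors already trim extreme genes, so leaving such genes out could hardly move the score. What stays open is that source, or another technical difference of this library or of its tubules. No biological explanation was tested for 1 library.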

How the results depend on the processing

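Nuclear protein-coding genes only, removal of the length and GC trend, and the score covariates were chosen only after the results were seen. The planned DESeq2 alternative was not run. Against 22 genes in proximal tubule, no filter called 80, the stricter filter 36, sample quality weights 40, 1 fit of all 15 libraries 123 and an adjusted p under 0.1 called 46, all including the 22; the segment score as a covariate called 0. Median-of-ratios scaling called 22, nuclear protein-coding genes 23, the length and GC trend removed 19, the number series as a covariate 23 and the second number series alone 20, of which 7 are shared. Leaving out 1 library gave 2 (without wild-type replicate 1) to 18. Against 13 higher and 9 lower, the second number series alone gave 18 and 2, 1 fit of all libraries 92 and 31, and leaving out 1 library from 1 and 8 (wild-type replicate 3) to 9 and 1 (knockout replicate 7). In distal tubule no filter called 4 genes and the other alternatives run called 0. For the interaction, no filter called 1, leaving out 1 library gave 0 to 1, and a trial quasi-likelihood test, not part of the results, called some. Between segments 5618 to 7474 were called, and with the replicate block 5840. Libraries of the same replicate number were no more alike than others. Same-number correlations were −0.014, −0.045 and 0.032 in wild type (other pairs −0.114 to 0.117) and −0.134 and −0.279 in knockout (other pairs −0.143 to 0.346). These few pairs of different segments cannot settle whether same-number libraries share an animal.

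Against 10 lists in proximal tubule, 7 up and 3 down, an estimated correlation called 0, no filter 16 (7 up, 9 down), with more lists tested, and the segment score as a covariate 8, with the balance turned (3 up, 5 down). Against 11 in distal tubule, an estimated correlation called 0, the collecting duct score as a covariate 5, and leaving out 1 library 7 (without knockout replicate 5) to 17 (without knockout replicate 6).

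Cldn10 in proximal tubule stayed at −10.96 to −10.5 with 1 library left out, but was not called without any 1 knockout library. Nor was it called in the second number series alone (−10.65), where samples are fewer, or with the segment score (−10.68, with SE 1.89 against 1.65). Its adjusted p ran from 3.26e-07 to 0.456 over the alternatives. With the score its unadjusted limma p was 8.46e-05, against 1.84e-05 in the main fit. The adjusted p of 0.456 also reflects weaker p values of other genes, as 0 genes were called in that fit. Cldn10 in distal tubule, at −1.34 and from −2.315 to −0.4075 with 1 library left out, turned to 0.0651 with the collecting duct score. With knockout libraries in place of wild type, Cldn10 between segments turned to −2.56, since Cldn10 has 0 counts in the proximal libraries of that comparison. Cldn2 in proximal tubule was −0.0103 in the second number series, −0.0274 with the segment score, and −0.00848 to 0.119 with 1 library left out.

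Other claudins that were not called changed sign. Cldn12 in proximal tubule was −0.0149 with the length and GC trend removed, and Cldn8 in distal tubule −0.0251 with quality weights and −0.0558 with that trend removed. With 1 library left out, proximal Cldn1 ran from −0.694 to 0.0291, Cldn6 from −1.24 to 0.0879 and Cldn12 from −0.00388 to 0.113; distal Cldn2 ran from −0.727 to 0.415, Cldn4 from −0.0595 to 0.363, Cldn8 from −0.0626 to 0.124 and Cldn19 from −0.374 to 0.644. Where no reason is given, the cause was not tested. Depth limits Cldn10 and Cldn2 in distal tubule, with 0 to 24 and 2 to 32 counts per library.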

Other observations

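The tests of segment, number series and linked genes were chosen only after the results were seen, and the counts over other splits were set beforehand.

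Genes of glutathione and xenobiotic defence moved both ways in proximal tubule. Of 27 tested, Gsta4 and Gsta2 fell over all genes, and 4 were higher and 4 lower adjusted over the list alone; fry for a change in either direction gave an adjusted p of 0.00083, while camera did not call the list. Lpl and Abcc4 had the same sign in both segments, with 1.89 and 0.53 for Lpl and 1.243 and 0.69 for Abcc4 on the log2 scale, in proximal and distal tubule. In distal tubule neither passed the test. By the z of both segments combined they ranked 1 and 2 of 11579 genes, which favours genes that agree. Over these genes without Cldn10, the changes in the 2 segments had a correlation of only 0.061. The pair is therefore no sign of a change shared between the segments in general.

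camera called straight-segment genes higher and early-segment genes lower in proximal knockout libraries, but neither call held with an estimated correlation (adjusted p = 0.144 and 0.350), and 2 of 13 and 0 of 16 genes passed over all genes. The straight minus early score was −0.854 ± 0.726 in wild type (SD, n = 4) and 1.139 ± 0.754 in knockout (SD, n = 3). The number series is argued against as the source, since within the second series alone the straight-segment median was 1.71. More late proximal tubule in the knockout pools may explain part of the shift: over 7587 genes outside the lists, the slope on the score among wild-type libraries alone correlated with the knockout change at 0.273, the highest of 24 orders of the wild-type scores, with 0.271 for the next. An effect of the genotype on these genes stays open and was not tested apart from it; with the score as a covariate 0 genes were called. That fit cannot part the score from genotype, as the score ran from −1.699 to −0.156 in wild type and from 0.413 to 1.918 in knockout. The 15 genes named first, of which Atp11a and Acy3 are part of the score, kept their sign with a median size ratio of 0.847 and a median SE ratio of 1.76, and 9 shrank, such as Akr1c14 (2.90 to 0.905), Ace (2.16 to 0.672) and Lpl (1.89 to 1.09), while Cyp4a12a (1.47 to 2.34), Abcc4 (1.243 to 1.81) and Gsta4 (−2.30 to −2.55) were among those that grew.

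Abcc4 and Tmtc4, near Cldn10, had log2 changes above 0 in both segments, but only Abcc4 in proximal tubule passed over all genes. Of 23 genes within 10 Mb tested in both, these 2 had a combined z over 3 in size with 1 sign, against 184 of 11579 genes in all. DNA linked to the targeted allele, such as flanking sequence of the strain the allele was made in, may account for these 2. Elsewhere, 4.64% of 11108 windows of as many genes held as many. These windows overlap, and the window size and cut were chosen after the results were seen, so this share is not an independent test. Of the 23 genes, 9 had the same sign in both segments, and their changes had a Spearman correlation of −0.002 between the segments. Within a segment, fry for a change in either direction called the neighbours of Cldn10 in both (adjusted p = 0.00474 in proximal and 0.0432 in distal tubule). A local effect of the allele itself stays open and was not tested.

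For the 22 genes of proximal tubule, 1 of 35 splits of the samples, the real one, gave as many and the highest other gave 2. This argues against chance but cannot exclude it, since 1 of 35 is the lowest share these splits can reach. Nor do the splits part genotype from another difference between the pools. For the 6631 genes between segments it was also 1 of 35 splits, with a highest other of 0. Every other split put proximal and distal libraries in the same group, which widens the spread. The 0 is therefore no measure of how many genes chance would call. Chance remains a full explanation for the number of lists called, 10 in proximal tubule (11 of 35, highest other 16) and 11 in distal tubule (8 of 35, highest other 13). These splits compare only how many lists were called. They do not weigh which lists moved or how far, so they decide nothing about any single list. For the 0 genes of distal tubule (35 of 35 splits, highest other 11) and the 0 genes of the interaction (100 of 100, highest other 3), a count of 0 is met by every split, so the splits say nothing about chance. The distal split with 11 genes set wild-type replicates 3 and 4 and knockout replicates 6 and 8 against the rest. It was singled out as the highest after the counts were seen, so chance may account for it. A structure other than genotype stays open. Of genes picked after their values were seen, Nr1d2, a clock gene, had 1.86 to 3.48 (log2 of CPM + 0.5) in these 4 and 3.93 to 4.97 in the others, and Egr1, an early response gene, 2.66 to 3.22 and 3.54 to 3.91, while Per3, another clock gene, overlapped. What set these libraries apart was not tested.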
